A study of Bos taurus with 16 samples.

How the data were processed

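The series holds 16 RNA-seq libraries from biopsies of bovine endometrium, 4 from each of days 5, 10, 14 and 18 after timed insemination of synchronised Holstein heifers. RNA was captured by its poly(A) tail and made into stranded libraries, per the labels' protocols. The authors deposited 1 table of raw read counts per gene for each library, not normalised, in the layout of the STAR aligner, with an unstranded count and 2 stranded counts per gene. FastQC, STAR and edgeR are named in the submitters' processing notes without versions, and the genome build and annotation are not given in the sources used here. Each table starts with 4 summary lines that name no gene, and these stayed out of library sizes and tests. Of the reads counted in genes, as ambiguous or as without a gene feature, between 23.1% and 33.4% had no gene feature on the counted strand. Whether these lay between genes or in uncounted parts of genes, such as introns, is not known here. The line for reads that map to several places is 0 in every library, so how reads shared by near-identical genes were treated is unknown, and values of such genes are uncertain.

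The stranded column with the larger sum was used, under a rule set before the data were examined that it hold at least 80% of both stranded columns in every library. It held between 98.3% and 98.6% of them, and the other column between 1.35% and 1.72%. Gene totals ran from 18959090 to 24291006 reads per library. Groups were taken from the labels. No 2 libraries of a day agreed within sampling noise, since the smallest chi-square per degree of freedom over 24 pairs was 37.2. The labels give no batch or date, so none could be tested. The labels number the replicates 1 to 4 within each day without saying that a number is shared across days. Deviations of same-numbered libraries from their day means correlated across genes at 0.12 to 0.32 in all 4 pairs of days 5 and 10, the highest mean of the 24 ways to match these libraries (one-sided exact permutation p = 0.0417, adjusted over the 6 pairs of days 0.25). For this pair of days alone all 4 correlations were over 0.1, so its result is also given with the replicate number as a block. That this was so for days 5 and 10 was seen only after the blocked and unblocked counts had been computed.

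Genes were filtered with edgeR's filterByExpr by day, which left 16331 of 27607 IDs, scaled by TMM and fitted with edgeR's quasi-likelihood method with robust estimation, all 4 days in 1 fit. Days were compared by contrasts, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 CPM for correlations, principal components and positions used a prior count of 2. The SE of a log2 fold change was its size divided by the square root of its F value. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9. The procedure was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. For day 10 against day 5 it recovered 16% and 76% of them, with 3 false calls among 95. Simulated genes varied independently, the changed ones had a mean CPM of at least 1 on the log2 scale, and no library stood apart. The shares recovered may therefore not hold for the real libraries.

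The any-day test and the comparisons of consecutive days were fixed before the data were examined. The other 3 pairs of days, the positions and the leaving out of 2 or 3 libraries that stand apart were added afterwards. Alternatives tried were RLE and upper-quartile scaling, no filter beyond 1 read, a stricter filter of 10 reads in each library of a day and a mean of 1 log2 CPM, unstranded counts, edgeR without robust estimation, a term for the replicate number, limma-voom with library weights, DESeq2, a fit of only the days compared, and leaving out each library in turn.

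The rule for named genes, fixed beforehand, took genes past the threshold with a mean of at least 1 log2 CPM and no overlap between the libraries of both days, by size of change. Its part on gene symbols, the 33 gene lists fixed beforehand and the genes to be followed by name could not be used, because 0 of the 27607 IDs matched the reference table, the NCBI RefSeq genes of assembly ARS-UCD2.0. For that reason 2 risen and 2 fallen IDs are named per comparison, and no gene list was tested.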

Results

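Gene expression was measured in endometrium, the inner lining of the uterus, of Holstein heifers on days 5, 10, 14 and 18 after timed artificial insemination. Each of the 16 libraries came from a biopsy of an animal assigned at random to its day, per the labels, with 4 animals per day. The study's title sets these days in the context of uterine secretion with an early embryo in the uterus, before implantation. The labels used here do not say for each animal whether an embryo was recovered, and day 0, which they also name, was not analysed here. Between 18959090 and 24291006 reads per library were counted in genes, and 16331 of the 27607 gene IDs had enough reads to be tested. The files name genes by Ensembl ID alone and do not pair them with symbols, so genes are given by ID and nothing is said of their function.

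The first question was how closely animals of 1 day resembled each other. Libraries of day 10 had a mean Pearson correlation with each other of 0.966 across genes on the log2 CPM scale, and libraries of day 14 of 0.958, where CPM is a read count relative to the scaled total of its library. The mean was lower within day 5, at 0.919, and within day 18, at 0.893. Day 18 libraries correlated more with those of days 5, 10 and 14, at means of 0.901, 0.914 and 0.918, than with each other. Between days 5 and 10 the mean was also 0.919. For days 10 and 14 the mean within the day was above that with every other day. Day 5 replicate 3 and day 18 replicate 2 had the lowest mean correlation with all other libraries, 0.859 and 0.855, against 0.916 or more for each of the other 14. In day 5 replicate 3, 1986 genes lay more than 4-fold from the mean of the other day 5 libraries, and in day 18 replicate 2 the number was 1742 against its own day. Day 18 replicate 3 differed in another way. Its highest correlation, 0.978, was with day 5 replicate 4, and 1123 of its genes lay more than 4-fold from the other day 18 libraries. These 3 libraries enter every comparison below unless stated, and the groups are those of the labels.

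**Figure D1:**
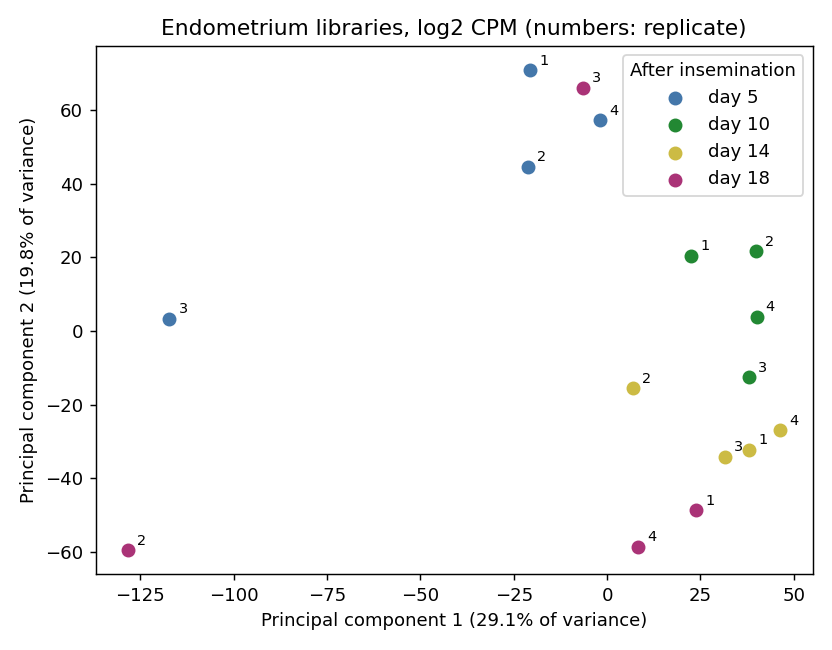
First and second principal components of log2 CPM over 16331 genes, with 29.1% and 19.8% of the variance on the axes, for the 16 libraries coloured by day and numbered by replicate. Day 5 replicate 3 and day 18 replicate 2 lie alone at the left, and day 18 replicate 3 lies among day 5 replicates 1, 2 and 4.

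Day of biopsy took up 32.3% of the squared distance between libraries over all 4 days. Random sets of libraries also take up a share, so this is not the size of a day effect alone. Of all 2627625 ways to part the 16 libraries into 4 sets of 4, 6256 gave a share as large (one-sided exact permutation test, p = 0.00238). For single pairs of days the share ran from 16.6% for day 18 against day 5 to 33.1% for day 14 against day 5. At the low end, 9 of 35 splits gave a share as large. No pair passed the threshold after Benjamini-Hochberg adjustment over the 6 pairs, where the smallest adjusted exact p was 0.0686. With 35 splits per pair, the smallest unadjusted p that could be reached was 0.0286.

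Across all 4 days, 35 genes differed on at least 1 day by edgeR's quasi-likelihood F-test with Benjamini-Hochberg adjustment. Of these, 14 had their highest mean on day 10, 13 on day 5, 5 on day 14 and 3 on day 18. The gene with the smallest adjusted p, 0.00325, was ENSBTAG00000043570, which averaged 448 CPM ± 177 (SD, n = 4) on day 5, 2686 ± 852 on day 10, 1177 ± 355 on day 14 and 351 ± 44.4 on day 18. The 4 day 10 libraries lay above all 12 others for this gene. The count of 35 depended strongly on the tool and on single libraries. DESeq2 gave 2297 genes and limma-voom with library weights 4460. Leaving out any 1 of the 16 libraries moved it by more than 1.5 times, to between 4, without day 5 replicate 1, and 1237, without day 18 replicate 3.

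Day 10 was compared with day 5 to follow the first step of the time course. Of the tested genes, 16 rose and 7 fell, and 20 of these 23 changed at least 2-fold. Among the risen genes, ENSBTAG00000021118 went from 0.268 CPM ± 0.180 (SD, n = 4) on day 5 to 110 ± 64.3 on day 10, a log2 fold change of 8.67 ± 1.49 (SE, adjusted p = 0.0491 by edgeR). ENSBTAG00000050427 rose by 3.51 ± 0.61 on the log2 scale, from 2.69 to 30.8 CPM, with the same adjusted p of 0.0491. Among the fallen genes, ENSBTAG00000014498 had a log2 fold change of -4.62 ± 0.76, from 23.0 to 0.933 CPM (adjusted p = 0.0440), and ENSBTAG00000016819 of -4.60 ± 0.73, from 33.3 to 1.37 CPM (adjusted p = 0.0375). Each of the 4 genes separated the 4 libraries of one day from the 4 of the other, as the rule for naming genes required. Their calls were lost in 11, 11, 9 and 9 of 21 alternatives in the order given. More genes rose than fell in 20 of 29 alternatives, fewer in 7, and 2 called none. Among the 7, DESeq2 called 512 risen and 665 fallen genes, limma-voom 1716 and 1958, and edgeR without day 5 replicate 3 and day 18 replicate 2 called 55 and 93. At an unadjusted p under 0.05 the balance was the other way, with 1416 higher and 1826 lower, and more were lower in all 29 alternatives. Deviations of same-numbered libraries of these days correlated weakly, a pairing not established after adjustment (one-sided exact permutation test, adjusted p = 0.25). It is not excluded either, since the unadjusted p of 0.0417 was the smallest that 24 ways to match allow. With the replicate number as a block edgeR called 1 gene. The folds of the 4 genes named stayed close to those above, at 8.85, 3.53, -4.73 and -4.50 on the log2 scale in the order given, with adjusted p from 0.0621 to 0.117. With the block in a fit of only days 5 and 10 it called 3 genes, none of them among the 23, and the adjusted p of the 4 named ran from 0.0557 to 0.0802. Leaving out any of the 16 libraries moved the count by more than 1.5 times. It was 0 without day 5 replicate 1 or 2, 1 without day 5 replicate 4, 12 without day 5 replicate 3, 2 to 5 without a day 10 library and 8 to 15 without a day 14 library. Without day 18 replicates 1, 2, 3 and 4 in turn it was 35, 224, 97 and 14.

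Between day 10 and day 14 no gene passed the adjusted threshold with edgeR, where the smallest adjusted p was 0.118. At an unadjusted p under 0.05 there were 948 genes, 5.80% of those tested, where chance alone gives about 5%. That number depended on the fit: it was 563 to 1257 with 1 of the 16 libraries left out, 1733 without day 5 replicate 3 and day 18 replicate 2, 2078 of 15717 in a fit of only these days and 2666 with limma-voom. DESeq2 called 58 genes and limma-voom 86, and edgeR called 1 without day 14 replicate 4. Without all 3 libraries that stand apart edgeR called 115, with 2223 at an unadjusted p under 0.05. Gene ENSBTAG00000043570 had a log2 difference of -1.19 ± 0.31 (SE, adjusted p = 0.610 by edgeR), and ENSBTAG00000021118 of -0.46 ± 1.01 (adjusted p = 0.974). In counts simulated from the depths, means and fitted dispersions, the same test found 82% of genes changed 4-fold and 17% of those changed 2-fold. There genes varied independently and no library stood apart, so these shares may not hold for the real libraries. Larger fitted differences also missed the threshold, such as 2.94 ± 0.68 on the log2 scale for ENSBTAG00000016819 (SE, adjusted p = 0.573 by edgeR).

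Between day 14 and day 18 no gene passed the threshold with edgeR either, where the smallest adjusted p was 0.0790. At an unadjusted p under 0.05 there were 1857 genes, 11.4% of those tested, of which 1320 were higher on day 18 and 537 lower. The total was 957 without day 18 replicate 2 and 2585 without day 18 replicate 1, the lowest and highest with 1 library left out, 1128 of 15675 in a fit of only these days and 892 with limma-voom. More were higher than lower in all 28 alternatives, though by 722 to 707 without the 3 libraries that stand apart. DESeq2 called 285 genes and limma-voom 0, and edgeR called 1 without day 14 replicate 2 and 1 without day 18 replicate 4. Gene ENSBTAG00000050427 averaged 55.0 CPM ± 27.6 on day 14 and 4.66 ± 3.42 (SD, n = 4) on day 18, a log2 difference of -3.56 ± 0.60 (SE, adjusted p = 0.190 by edgeR). Gene ENSBTAG00000021118 was at 16.7 CPM or more in each day 14 library and at 11.99 CPM or less in each day 18 library, with 0 reads in day 18 replicate 2 (log2 difference -4.48 ± 1.17, adjusted p = 0.270 by edgeR). In simulated counts with these depths, 74% of genes changed 4-fold and 20% of genes changed 2-fold were found. As no simulated library stood apart, these shares may not hold for the real ones.

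The remaining 3 pairs of days were added after the data were examined. Day 14 differed most from day 5 in the number of genes, with 184 that rose and 183 that fell, 239 of them at least 2-fold. All passed narrowly, since the smallest adjusted p was 0.0363 by edgeR. The smallest was 0.00971 for day 10 against day 5 and 0.00440 for day 18 against day 10. Adjustment was within each pair of days and not over the pairs. ENSBTAG00000046768 had 3 reads in all 4 day 5 libraries together and 11774 on day 14, a depth-scaled ratio of 3449 with a 95% counting interval of 1180 to 16725, which covers counting error alone. Of the 3 reads 2 came from day 5 replicate 3, without which the ratio was 8419 (interval 1511 to 332543) and the adjusted p by edgeR was 0.0527, against 0.0465 with it and 1.08e-06 to 0.124 over 20 alternatives. ENSBTAG00000021118 rose by 8.21 ± 1.47 on the log2 scale (SE, adjusted p = 0.0363 by edgeR). The fallen genes with the largest change were ENSBTAG00000035171, with a log2 fold change of -8.90 ± 2.13 and a fall from 206 to 0.424 CPM, and ENSBTAG00000009014, with -6.28 ± 1.36 and a fall from 266 to 3.41 CPM (adjusted p = 0.0465 for both by edgeR). The calls of these 4 genes were lost in 10, 8, 9 and 9 of 20 alternatives in the order given. On day 5 ENSBTAG00000035171 was at 3.71 CPM in replicate 3 and at 230 to 305 CPM in the other 3 libraries, and on day 18 it was at 149 CPM in replicate 3 and at 2.14 CPM or less in the other 3. The count of 367 went to 0 without day 5 replicate 1, 2 or 4, day 14 replicate 1, 3 or 4, or day 10 replicate 1 or 2, to 1 without day 14 replicate 2 or day 10 replicate 4, and to 58 without day 10 replicate 3. It rose to 769 without day 5 replicate 3, and to 754, 1235, 1275 and 847 without day 18 replicates 1, 2, 3 and 4 in turn. DESeq2 called 2225 genes and limma-voom 4141. With the replicate number as a block edgeR called 0, and with no filter 64. It called 1145 in a fit of only these days and 3169 without all 3 libraries that stand apart.

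**Figure D2:**
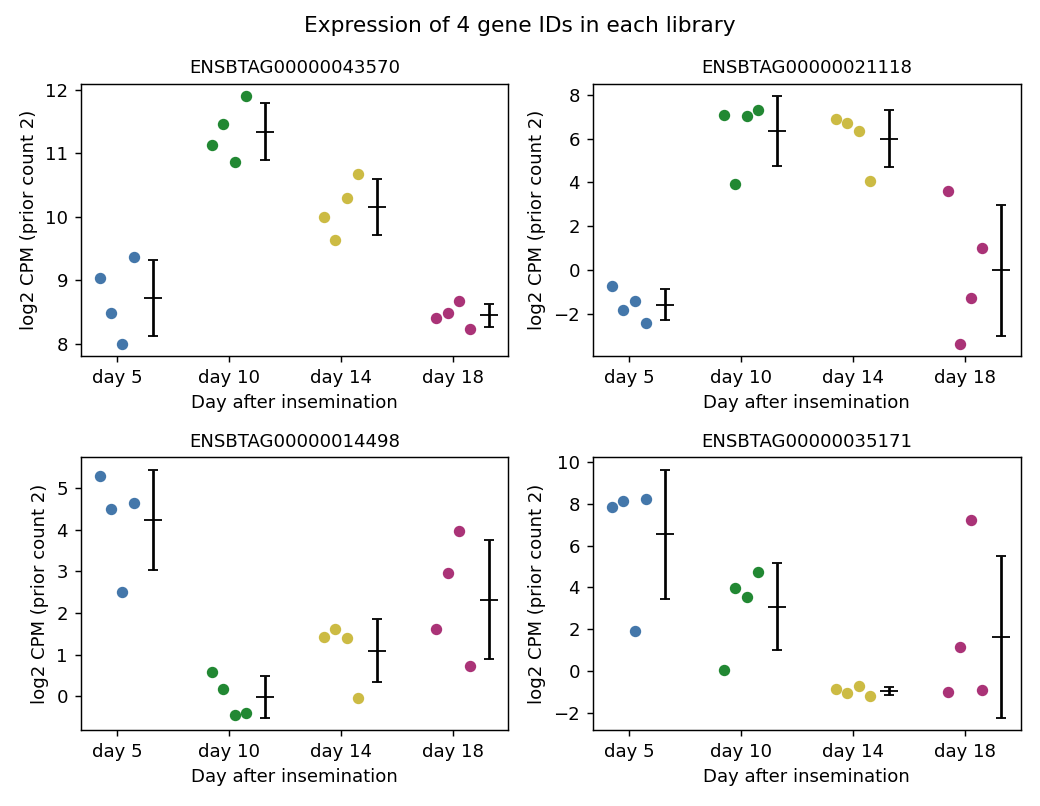
Expression of 4 gene IDs as log2 CPM (prior count 2) in each library by day, with points in the order of replicates 1 to 4 and bars for the mean and SD of 4 libraries. ENSBTAG00000043570 is highest on day 10, ENSBTAG00000021118 lies above 3.9 in every library of days 10 and 14, and ENSBTAG00000035171 is low in day 5 replicate 3 and high in day 18 replicate 3.

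Day 18 was compared with day 10, and 4 genes rose and 12 fell. ENSBTAG00000030974 rose by 2.78 ± 0.44 (SE) on the log2 scale, from 5.38 to 37.1 CPM (adjusted p = 0.0374), and ENSBTAG00000008333 by 2.34 ± 0.38, from 1.94 to 9.84 CPM (adjusted p = 0.0423), both by edgeR. ENSBTAG00000007125 had a log2 fold change of -3.55 ± 0.55, from 173 to 14.8 CPM (adjusted p = 0.0374), and ENSBTAG00000043570 of -2.94 ± 0.33 (adjusted p = 0.00440). The last passed in all 20 alternatives. The calls of ENSBTAG00000030974, ENSBTAG00000008333 and ENSBTAG00000007125 were lost in 6, 8 and 6 of the 20, where the highest adjusted p was 0.252, 0.172 and 0.107. Both risen genes lost theirs in a fit of only days 10 and 18 and without day 10 replicate 1, 2 or 4 or day 18 replicate 2. The count of 16 went to 3 without day 10 replicate 4 or day 18 replicate 2, 4 without day 10 replicate 2, 5 without day 18 replicate 4, and 9 without day 10 replicate 3. It was 5, 5, 47 and 6 without day 5 replicates 1, 2, 3 and 4 in turn and 4 without day 14 replicate 1. More genes fell than rose in 25 of 28 alternatives. In the other 3, DESeq2 called 501 risen and 266 fallen genes, and edgeR called 19 and 17 without day 18 replicate 1 and 136 and 113 without day 18 replicate 3. At an unadjusted p under 0.05 the balance was the other way, with 1603 higher and 783 lower, and more were higher in all 28 alternatives. Limma-voom called 6 and 22. Between day 18 and day 5 edgeR called 0 genes, with 2230 genes (13.7%) at an unadjusted p under 0.05. With 1 library left out this ran from 1309, without day 18 replicate 4, to 4150, without day 18 replicate 3, and it was 865 of 15686 in a fit of only these days. DESeq2 called 172 and limma-voom 0, and edgeR called 861 without day 18 replicate 3 and 1 without day 10 replicate 4. Without all 3 libraries that stand apart edgeR called 2417, with 5005 at an unadjusted p under 0.05.

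To place each library in the course from day 5 to day 14, its mean log2 CPM over the 184 risen genes minus that over the 183 fallen genes was rescaled so that the day 5 mean was 0 and the day 14 mean 1. This measure was also added after the data were examined, and because the genes were chosen on the day 5 and day 14 libraries, it overstates how far those days part. On 100 genes per direction ranked without the library placed, day 5 libraries lay at 0.0731 to 0.479 and day 14 libraries at 0.777 to 1.01. Day 10 replicate 3 lay at 0.819 on 100 genes per direction ranked with all libraries. Day 14 replicates 2 and 4 lay at 0.777 and 0.804 on genes ranked without them, so these values do not share a scale. On the called genes day 10 replicate 3 lay at 0.834 and the lowest day 14 library at 0.939. Day 10 averaged 0.694 ± 0.108 (SD, n = 4), and 147 of the risen and 148 of the fallen genes had a day 10 mean nearer to day 14 than to day 5. Day 18 averaged 0.514 ± 0.372, with replicates 1 and 4 at 0.860 and 0.799 and replicates 2 and 3 at 0.285 and 0.111. The difference between days 18 and 10, -0.180, was smaller than the SD of day 18 and larger than that of day 10, and it did not pass a two-sided exact permutation test (p = 0.429, n = 4 per day). The sign of this difference changed in fits that left out libraries, where the genes were also called anew. The means of days 18 and 10 were then 0.758 and 0.678 without day 18 replicate 3 and 0.938 and 0.673 without all 3 libraries that stand apart. They were 0.342 and 0.682 without day 18 replicate 1. How far the change of genes, rather than of libraries, moved these means was not tested.

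**Figure D3:**
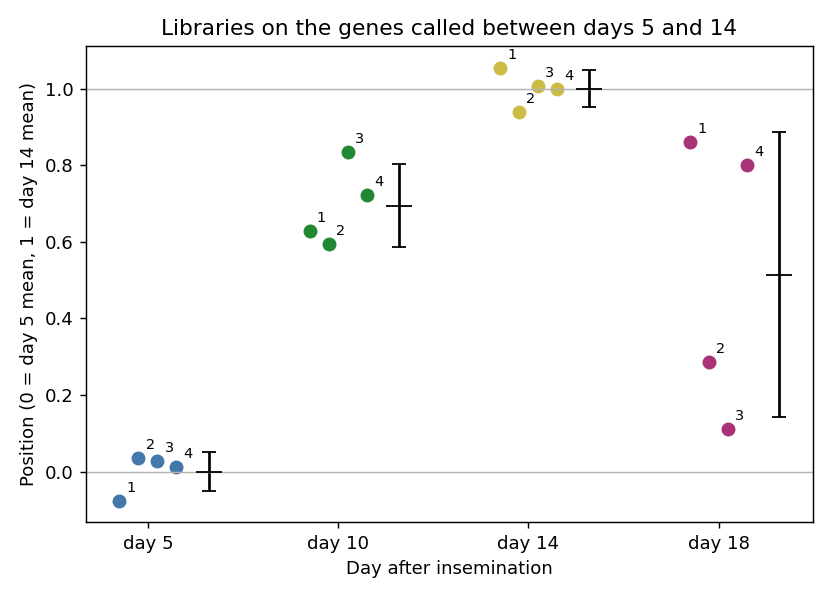
Position of each library on the 367 genes called between days 5 and 14, where 0 is the day 5 mean and 1 the day 14 mean, by day, with replicate numbers and bars for the mean and SD of 4 libraries. The day 10 libraries lie between 0.593 and 0.834, and the day 18 libraries between 0.111 and 0.860.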

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

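Of the tests here, thinning and the removal of the largest genes were set up before their results were seen, and all others, the counts of other splits included, were written down after. For 5 measures or genes 1 library lay far from the other 3 of its day, among 80 groups of 4 examined, where chance alone flags about 1 group in 20, or 4. On day 5 these were the share of unmapped reads in replicate 3, 9.42% against 8.40% to 8.46%, its mean correlation with all other libraries, 0.859 against 0.922 to 0.934, and its log2 CPM of ENSBTAG00000035171, 1.93 against 7.84 to 8.25. On day 10, replicate 2 had a log2 CPM of 3.95 for ENSBTAG00000021118, against 7.02 to 7.31. On day 14, replicate 4 had -0.0395 for ENSBTAG00000014498, against 1.40 to 1.61. Reads not used in the comparisons made up a median of 28.7% without a gene feature and 1.53% of gene reads on the other strand, and whether they carry a signal was not tested.

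The first pattern is that day 18 replicate 3 lies with the day 5 libraries. Its gene total of 21757330 reads was above the median of 20480214 over all libraries, which argues against low depth. A wrong label on this library alone remains a possible explanation, since its mean correlation with day 5 replicates 1, 2 and 4 was 0.971, within the 0.961 to 0.972 found among those 3. Whether its label was exchanged with that of day 5 replicate 3 could not be decided: the split of the 8 libraries that exchanges them called 2423 genes, against 0 for the real split and at most 1 for any other. Day 5 replicate 3 correlated at 0.857 to 0.878 with day 5 replicates 1, 2 and 4. With day 18 replicates 1, 2 and 4 it correlated at 0.838 to 0.864, and its highest correlation, 0.887, was with day 14 replicate 2. These overlapping ranges cannot decide for or against an exchange. Day 18 replicate 2, which also stands apart, had its own highest correlation, 0.891, with day 5 replicate 2. The position of day 5 replicate 3 between days 5 and 14 depended on how it was measured, at 0.48 on genes ranked without it and at 0.54, 0.37 and 0.68 on all, rising and falling genes chosen without either library. No biological explanation was tested, since the labels give no pregnancy status or hormone level for each animal, and an animal whose endometrium differed on day 18 stays open.

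The second pattern is that day 5 replicate 3 and day 18 replicate 2 stand apart from all other libraries. With all libraries thinned to the same depth, both still had the lowest mean correlations, 0.0566 below the next library, against 0.0567 before. With the 50 largest genes of each library removed, 161 of 16331 in all, the gap was 0.0588. Both changes were small, as thinning went to 1.8e+07 reads from 18959090 to 24291006, so a steady gap says little by itself. Gene totals of 19115995 and 20668927 reads in the 2 libraries lay within the range of the others, which argues against low depth. A part of large genes is not excluded. Other library measures moved with the pattern: both had the fewest genes detected (18348 and 18274), the highest share of counts in the 10 largest genes (10.4% and 11.9%) and the lowest scaling factors (0.748 and 0.836) of the 16, and day 18 replicate 2 had the highest share of unmapped reads (11.0%). One shared source in both libraries may or may not be present: their deviations from their day means correlated at r = 0.30 across genes, which are not independent replicates, while other pairs of different days reached 0.47. RNA quality and the mix of cells in the biopsy were not tested and stay open, and no biological explanation was tested.

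Other splits of the same libraries bear on each count of genes. For day 10 against day 5 (23 genes), day 14 against day 5 (367) and day 18 against day 10 (16), only the real split, 1 of 35, gave as many, and the highest other count was 0. A share of 1 in 35, 0.0286, is the smallest this design can give, and it is 0.0571 after adjustment over the 6 pairs of days, so chance is not excluded over all 6. The 6 include the 3 pairs with a real count of 0, whose shares are fixed. With these included, no adjusted share under 0.0571 could result, so the adjustment cannot decide. If the replicate numbers paired the libraries of days 5 and 10, which is not established, 8 of the 35 splits would part all 4 pairs. Of these 8 the real one alone gave as many genes, with 0 the highest other. That is too few splits for a share under 0.05. Other splits set both libraries of a number together. For day 14 against day 10, day 18 against day 14 and day 18 against day 5 the real count is 0, so 35 of 35 splits give as many by construction and the test says nothing of chance. The highest other counts were 0, 0 and 2423. For any day, 4 of 100 drawn groupings, the real one included, gave 35 genes or more, and the highest other gave 762. Counts of 762 and 2423, many times the real ones, point to a structure of the samples that the days do not describe: in both groupings day 18 replicate 3 is set with day 5 replicates 1 and 2. That alone did not give calls, since 4 of the 5 splits of days 5 and 18 that set these 3 libraries together called 0 genes, as did 1 of the 3 such groupings of all days.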

How the results depend on the processing

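The comparisons added after the data were examined, the positions, the 2 fits that leave out libraries that stand apart, the leaving out of libraries of days not compared and the blocked fit of days 5 and 10 alone were chosen after seeing the data. Counts are given in the order any day, 10 against 5, 14 against 10, 18 against 14, 14 against 5, 18 against 10 and 18 against 5, where the counts reported are 35, 23, 0, 0, 367, 16 and 0. Under RLE and upper-quartile scaling, the stricter filter, unstranded counts and edgeR without robust estimation, all 7 stayed within 1.5 times. With no filter the 10 against 5, 14 against 5 and 18 against 10 counts were 9, 64 and 7, with 21807 genes tested in place of 16331. DESeq2 gave 2297, 1177, 58, 285, 2225, 767 and 172. Limma-voom gave 4460, 3674, 86, 0, 4141, 28 and 0, with library weights of 0.199 for day 5 replicate 3, 0.247 for day 18 replicate 2 and 0.392 for day 18 replicate 3. A fit of only the days compared gave 230 for 10 against 5, 1145 for 14 against 5 and 4 for 18 against 10, and 0 for the other 3 pairs. The cause of these differences was not tested.

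Leaving out each of the 16 libraries in turn gave 4 to 1237, 0 to 224, 0 to 1, 0 to 1, 0 to 1275, 3 to 249 and 0 to 861. The highest of these for any day, 14 against 5, 18 against 10 and 18 against 5 came without day 18 replicate 3, and for 10 against 5 without day 18 replicate 2. With day 5 replicate 3 and day 18 replicate 2 both left out, the counts were 321, 148, 1, 0, 1638, 14 and 0. With day 18 replicate 3 left out as well they were 2688, 1543, 115, 0, 3169, 298 and 2417. All 23 genes called between days 10 and 5 and all 367 between days 14 and 5 stayed among the calls of both these fits. They leave day 18 with 3 or 2 libraries and were chosen because of what the libraries showed, so they measure how far the counts rest on 3 libraries and are not better estimates. The day 10 position ran from 0.551 to 0.709 with single libraries left out, lowest without day 10 replicate 3, and the day 18 position from 0.342 to 0.758, and it was 0.938 without all 3 libraries. Each position was taken on the genes called in its own fit, so the genes changed along with the libraries. Positions were not computed where a direction had under 10 calls, as with 10 of the 16 libraries left out, nor for other tools.

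Pairing by replicate number is not established for any pair of days, where the smallest adjusted p was 0.25 (one-sided exact permutation test). That value belongs to days 5 and 10, where the unadjusted p of 0.0417 was the smallest that 24 ways to match allow. The test therefore cannot exclude a pairing of these days. Over all days, deviations from the day means correlated across genes between -0.30 and 0.35 over 24 pairs with the same number, over 0.1 in 7 of them, and 3 of 16 libraries correlated best with their own number. With the replicate number as a block the counts were 8, 1, 0, 0, 0, 1 and 0, and 3 for 10 against 5 in a fit of only these days. Over 12 results for named genes and 244 alternative values, which leave out only libraries of the days compared, 148 kept the call, 96 lost it and 0 reversed. Where it was lost, the log2 fold moved by a median of 0.13 and at most 1.052, the latter for ENSBTAG00000046768 without day 5 replicate 3. ENSBTAG00000043570 between days 18 and 10 passed in all 20, with adjusted p from 2.02e-16 to 0.0232. The planned gene-list alternatives were not run. Depth limits genes of few reads most, such as ENSBTAG00000046768 with 3 reads on day 5.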

Other observations

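Both tests here were chosen after the positions of the libraries had been seen. The share of reads without a gene feature averaged 24.6% ± 1.54 (SD, n = 4) on day 5, 29.7% ± 1.47 on day 10, 30.2% ± 2.42 on day 14 and 27.6% ± 3.40 on day 18. Day 10 and day 14 were each above day 5 in a two-sided exact permutation test, p = 0.0286, the smallest that 4 against 4 allows, but the adjusted p over 24 tests of library measures was 0.137. On day 18 the share without a gene feature was 30.4% and 30.7% in replicates 1 and 4 and 24.6% and 24.7% in replicates 2 and 3. A hypothesis was that within days the share without a gene feature follows a library's position between day 5 and day 14, with day 5 and day 14 libraries placed on genes ranked without them. After subtracting the day means, Pearson's r over 16 libraries was 0.59 (exact permutation within days, p = 0.177) and Spearman's rho of ranks within days 0.25 (p = 0.449), and r was 0.63 without the 2 libraries farthest from the median share. The relation did not pass the threshold and remains open. The share of unmapped reads gave an exact permutation p of 0.0286 and an adjusted p of 0.137 in 3 comparisons: it averaged 8.68% on day 5, 7.89% on day 10, 7.86% on day 14 and 9.31% on day 18, and day 10 and day 14 lay below day 5 and day 18 above day 14.

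A further hypothesis was that the day 18 libraries as a group shift back along the change from day 5 to day 10. The difference between day 18 and day 14 was set against that between day 10 and day 5, which share no library. Across 16331 genes, which are not independent replicates, r was -0.51 and Spearman's rho -0.41, but 8 of the 70 labelled splits of the day 14 and day 18 libraries gave an r as low (one-sided exact permutation p = 0.114). It was -0.37 without day 18 replicate 3, -0.40 without replicate 2 and -0.09 without both, where 5 of 15 splits were as low. The test does not carry the hypothesis for the group, and most of the negative correlation came with replicates 2 and 3.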
